A study of Mus musculus with 9 samples.

How the data were processed

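Nuclei were isolated from the kidneys of 9 male mice, sorted for GFP and sequenced with Chromium single-nucleus libraries that count the 3' ends of transcripts. The authors deposited 2 tables of raw UMI counts per gene and nucleus, 1 for the control mice and 1 for the mice with ischemia-reperfusion injury (IRI). The submitters' processing notes name Cell Ranger, STAR, Seurat and the mm10 build, and their versions are not given in the sources used here. Whether the counts keep the strand of a transcript is not stated. Per the labels, v2 and v3 kits were both used and doublets were removed by gating at the sorter, but the kit of each library is not given. The cell barcodes of each library began either with the starts of the v2 set or with those of the v3 set. By this reading the 4 controls and day 28 mouse 1 had v2 barcodes, and day 28 mice 2 and 3 and both day 7 mice had v3 barcodes.

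Every value in the tables was a whole number, and each gene had a count in at least 3 nuclei of its table. The control table listed 17455 genes and the IRI table listed 19342, of which 16939 were in both. Genes of only 1 table, 516 and 2403, were left out of the comparisons because a gene missing from a table cannot be told from one dropped by that filter. Of 19858 gene symbols, 19563 (98.5%) were found in GENCODE mouse release 21 (GRCm38, the mm10 assembly), which supplied coordinates.

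The files used here hold no cell type annotation, so classes were rebuilt with scanpy 1.11.5 from the genes in both tables. Counts were scaled per nucleus and log-transformed. The 2000 variable genes chosen across libraries gave 30 principal components, 20 neighbours per nucleus and a Leiden partition at resolution 2 with random seed 0. The partition used the igraph implementation. The neighbour graph was computed in double precision, because in single precision the clusters depended on the processor. Seeds 1 to 4 were run as alternatives chosen after seeing the data, since the uninjured-state classes were found to depend on such details. Each of the 33 clusters was scored against marker lists by the mean log2 difference from the other clusters, with 10 CPM (UMIs of a gene per 1e6 UMIs of a sum) added. A cluster took the class with the highest score when that score reached 0.5, at least 3 markers were raised and no class of another kind scored 1.5 or more. For this the markers of distal convoluted and connecting tubule and of principal cells counted as 1 kind, distal, and those of uninjured and injured proximal tubule as 1 kind, proximal tubule. The minimum of 0.5 was set after the scores had been seen, and 2 proximal tubule clusters of IRI nuclei owe their name to it. They held 3.81% and 3.09% of the proximal tubule-like nuclei of the day 7 mice, 6.77%, 22.3% and 7.08% of those of the day 28 mice and at most 0.048% in any control. Classes are written as "-like" because they rest on these markers. The 6 unnamed clusters, with 2225 nuclei, carried markers of more than 1 class and were left out. Scrublet marked 25 nuclei (0.09%) as doublets, too few to have worked, so doublet calls were not used.

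UMI counts were summed per library over the proximal tubule-like (PT-like) nuclei, over the thick ascending limb-like (TAL-like) nuclei, and over PT-like nuclei of the 9 clusters whose proximal tubule score exceeded their injured proximal tubule score, called uninjured-state below. Sums were compared with edgeR 4.0.16 in R 4.3.3: TMM factors, filterByExpr, quasi-likelihood fits and F tests, with all 9 libraries in 1 fit. The threshold was a Benjamini-Hochberg adjusted p of 0.05. Gene CPM of the comparisons were taken over the genes tested and scaled by the TMM factors. CPM ratios between classes and CPM of distal-like nuclei used all UMIs of genes in both tables, without those factors. The standard error (SE) of a log2 change was its size divided by the square root of F. The comparisons were day 7 against control, day 28 against control and day 28 against day 7 in PT-like sums, day 28 against control in uninjured-state sums, and the mean of both IRI times against control in TAL-like sums. The PT minus TAL difference in the IRI effect was fitted on both sums with the library as a block. P-values from these fits measure the spread of these samples. On simulated data, 4-fold changes were recovered for 52% to 81% of genes and 2-fold changes for 7% to 24%, none in the wrong direction.

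There were 24 gene lists, tested with limma 3.58.1 camera at a preset inter-gene correlation of 0.01, with camera at an estimated correlation and fry beside it, and with adjustment over the lists. The uninjured-state comparison was planned only for data with an annotation of injured clusters, which the files used here do not hold. It was run instead on clusters chosen by the marker scores above, a choice that was not part of the plan. The other comparisons, the lists and the rule for named genes were fixed before the data were examined. The rule named, per comparison, the 8 largest rises and 8 largest falls with a mean of at least 20 CPM in the higher group and no overlap between libraries, without predicted gene models. It added up to 3 members per list with the smallest adjusted p, and always Krt20, Havcr1, Vcam1, Ccl2, Spp1, Lrp2, Slc34a1 and Hnf4a. Genes with 3 or fewer UMIs in a group are given as CPM, without a fitted fold, except in the closing list of genes that turned under alternatives. The values of 3 genes that this rule named are not reported here.

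Shares of nuclei per library were compared by two-sided exact permutation tests, with 126 splits for 5 IRI against 4 control mice and 10 splits for 3 day 28 against 2 day 7 mice. Shares of injury states could not be taken from an annotation. They were replaced by the percent of PT-like nuclei with at least 1 UMI of a gene after each nucleus had been thinned at random to 500 UMIs; nuclei with fewer were left out. Binomial floors and other counting limits cover counting error only.

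Alternatives included DESeq2 1.42.0, RLE factors, limma voom, other count filters, thinning to the smallest total, a minimum of 1000 UMIs per nucleus, leaving out each library, and replicate number as a block. Chosen after seeing the data were the barcode set as a term, the libraries of 1 barcode set alone, Leiden resolution 1 and the other seeds, and unnamed clusters counted under the class of their highest score. So were leaving out the nuclei with the most UMIs from the sums, shares without thinning, genes of either table with absent ones at 0, lists without the genes that named clusters, and leaving out genes covered by a gene on the other strand. A planned restriction to nuclei of the S3 segment was not run, because the files used here give no segment labels and the rebuilt classes do not separate that segment.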

Results

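Single-nucleus RNA counts covered 9 male mice: 4 controls, 2 mice at day 7 and 3 mice at day 28 after bilateral ischemia-reperfusion injury (IRI) with an 18 min clamp of the renal vessels. Control kidneys came from 3 sham-operated mice and 1 mouse without surgery (control 1), in which doxycycline-induced GFP marked nuclei of the whole nephron lineage. IRI kidneys carried a tamoxifen-induced recombinase driven by Krt20, a keratin gene of injured tubule cells, and a nuclear GFP that marked the descendants of Krt20-expressing cells. Reporter line and sort therefore differed together with injury in each comparison with control. Day 28 against day 7 was free of that difference. The tables held 27738 nuclei, 13116 from controls and 14622 from IRI mice, with 66996218 UMIs. Library totals were 7029488, 4982300, 9622439 and 1833617 UMIs for controls 1 to 4, 14641038 and 8718254 for the day 7 mice, and 2409411, 11668625 and 6091046 for the day 28 mice. The nuclear RNA Malat1 took 19.8% to 24.0% of UMIs in controls, 6.74% and 10.3% at day 7, and 16% to 17.6% at day 28.

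The first question was which cells each sort had delivered. Proximal tubule-like (PT-like) nuclei were the largest class, at 82.9% ± 10.7 (SD, n = 4) of control nuclei and 80.5% ± 5.76 (n = 5) of IRI nuclei (two-sided exact permutation p = 0.698). TAL-like nuclei, from the thick ascending limb that reabsorbs salt, made up 4.38% ± 3.61 and 3.48% ± 2.39 (exact permutation p = 0.690). Stroma-like nuclei were 2.90% ± 1.30 of IRI and 0.232% ± 0.126 of control nuclei (exact permutation p = 0.00794, the smallest that 126 splits allow). Endothelium-like nuclei were 1.71% ± 0.714 against 0.199% ± 0.119 and leukocyte-like nuclei 1.25% ± 0.591 against 0.0665% ± 0.0545 (exact permutation p = 0.0159 for both). With unnamed clusters counted under the class of their highest score, endothelium-like nuclei were 2.52% ± 0.600 against 1.29% ± 0.628 (exact permutation p = 0.0159). These 3 classes had an adjusted p of 0.0423 over 8 classes, and each IRI library lay above each control library. Distal-like, intercalated-like and podocyte-like shares differed by less than the spread between mice (exact permutation p = 0.611, 0.802 and 0.730). At day 28 TAL-like nuclei were 4.93% ± 1.88 (n = 3) against 1.31% ± 0.392 (n = 2) at day 7, with an exact permutation p of 0.1, the smallest that 10 splits allow, and an adjusted p of 0.4. That difference rests on an unnamed cluster with markers of TAL and distal tubule, which held 228 and 210 nuclei of the day 7 mice, 40, 99 and 52 of the day 28 mice and 2 of the controls. With unnamed clusters counted in that way, TAL-like nuclei were 7.94% ± 1.84 at day 28 and 7.20% ± 0.443 at day 7 (exact permutation p = 0.7). Whether the unnamed cluster with TAL and distal markers holds doublets was not tested. Among v2 libraries only day 28 mouse 1 was an IRI library; its stroma-like share exceeded the control mean by 3.58 points, its endothelium-like share by 1.14 and its leukocyte-like share by 0.578. The 3 calls ended when nuclei under 1000 UMIs were left out (exact permutation p = 0.0159, 0.0635 and 0.0238 for stroma, endothelium and leukocytes). They also ended without any 1 control (exact permutation p from 0.0179 to 0.0357). With an IRI mouse left out, 4 against 4, no p is below 0.0286 and a call needs that p in 5 of 8 classes, so none was possible; the 3 classes had it each time. Leaving out 1 library gave differences of 2.21 to 2.95 points for stroma, 1.22 to 1.69 for endothelium and 0.957 to 1.33 for leukocytes.

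**Figure D1:**
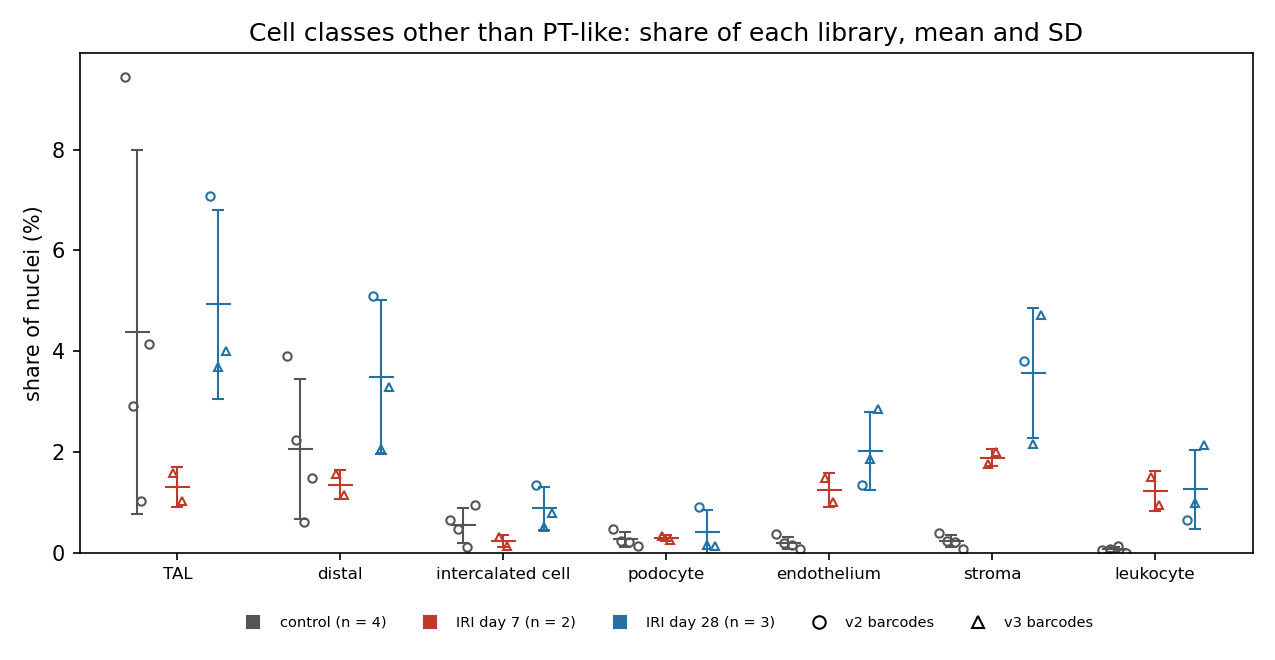
Percent of each library's nuclei in the rebuilt classes other than PT-like, with 1 point per mouse and bars at the group means. Stroma-like, endothelium-like and leukocyte-like shares were higher in each of the 5 IRI libraries than in any of the 4 control libraries.

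Day 7 was set against control to ask what Krt20-traced proximal tubule nuclei expressed in the week after injury. Genes of injured tubule rose: Havcr1, which encodes the injury marker KIM-1, had 951 ± 159 CPM (SD, n = 2) against 5.87 ± 2.85 (n = 4) in control, a log2 change of 7.35 (SE 0.42, adjusted p = 2.6e-07). Cd44, a hyaluronan receptor, rose from 1.70 ± 0.666 to 570 ± 26.2 CPM, a log2 change of 8.47 (SE 0.35, adjusted p = 3.1e-08). The adhesion gene Vcam1 rose by 5.18 (SE 0.41), Spp1, which encodes osteopontin, by 3.04 (SE 0.33), and the reporter's own gene Krt20 by 2.93 (SE 0.59, adjusted p = 0.0016). Slc34a1, the sodium-phosphate cotransporter of the proximal tubule, fell by 3.26 (SE 0.37, adjusted p = 3.2e-05), from 4912 ± 104 to 514 ± 7.75 CPM. The endocytic receptor gene Lrp2 fell by 1.39 (SE 0.27, adjusted p = 0.0011). For these 7 genes the libraries of the 2 groups did not overlap. All of them but Cd44 are among the markers that named the PT-like clusters. Some clusters of IRI nuclei entered the class by injury markers: 1 had a proximal tubule score of -2.31 and an injured score of 2.64. High injury markers in IRI PT-like sums were therefore favoured by that choice, and low Slc34a1 and Lrp2 were no bar to it. With and without the genes that named clusters, 15 gene lists had a camera call.

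Of 14264 genes tested in PT-like sums, 3713 rose and 3527 fell at day 7. Among the largest rises were Runx1 at 7.83 (SE 0.33), Ccbe1 at 7.5 (SE 0.43) and Styk1 at 7.48 (SE 0.43). The transcription factor gene Sox9 had 45.9 ± 0.207 CPM against 0.110 ± 0.220 in control, Sox11 36.2 ± 4.06 against 0.211 ± 0.293, and Traf1 34.3 ± 4.17 against 0.111 ± 0.223, each with 3 or fewer UMIs over all controls. Among the largest falls were Hdc, the histidine decarboxylase gene, at -7.09 (SE 0.73), Mas1 at -6.85 (SE 0.85), Serpine3 at -6.68 (SE 0.77) and Cyp4a14, a fatty acid hydroxylase gene, at -6.73 (SE 1.31). Apoc3 had 0.187 ± 0.264 CPM against 59.7 ± 39.2. Hnf4a, a transcription factor gene of proximal tubule identity, did not pass at day 7 (-0.55, SE 0.23, adjusted p = 0.060). No day 7 library had v2 barcodes and no control had v3, so no value within 1 barcode set exists for this comparison. With the barcode set as a term, which rests on day 28 mouse 1, 1938 genes passed, Havcr1 changed by 7.66, Vcam1 by 5.73 and Slc34a1 by -2.71, Lrp2, Rarres2, Cyp4a14 and Shcbp1l lost their calls, and Smcp turned from -6.78 to 0.38.

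Gene lists moved in blocks at day 7. Of 19 failed-repair PT markers, 18 rose and 1 fell, with Dock10 at 5.44 (SE 0.23), Cdh6 at 5.98 (SE 0.27) and Cp, which encodes ceruloplasmin, at 5.49 (SE 0.27). The camera adjusted p was 6.3e-11, against an adjusted p = 0.0554 with an estimated correlation. Acute injury markers rose for 17 of 24 (Anxa3 at 6.23, SE 0.27) and fell for 1. TGF-beta, matrix and integrin genes rose for 20 of 25, with the growth factor genes Pdgfd at 7.04 (SE 0.35) and Pdgfb at 2.79 (SE 0.22), and fell for 1. NF-kB and chemokine genes rose for 15 of 21, among them Nfkb1 at 3.46 (SE 0.22) and Il34 at 3.65 (SE 0.24). Cell cycle genes rose for 12 of 21 (Anln at 4.48, SE 0.36; Cenpf at 3.12, SE 0.45) and fell for 1, nephron progenitor genes rose for 11 of 18 (Sox4 at 5.02, SE 0.37) and fell for 1, immediate early genes rose for 10 of 15 (Fosl2 at 3.92, SE 0.29) and fell for 1, and podocyte and parietal markers rose for 5 of 7 (Ncam1 at 3.77, SE 0.34). With an estimated correlation these 7 lists had an adjusted p = 0.105, 0.0554, 0.106, 0.124, 0.0554, 0.279 and 0.105, in that order. Adjusted over the list alone, 18 failed-repair, 18 injury, 20 TGF-beta, 15 NF-kB and 12 cell cycle genes were higher.

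Metabolic and transport lists went the other way at day 7. All 10 gluconeogenesis and fructose genes fell, among them Fbp1, a rate-setting enzyme of glucose synthesis, at -3.20 (SE 0.34) and the fructokinase gene Khk at -3.71 (SE 0.40). Fatty acid oxidation genes fell for 21 of 25 (Acadm at -1.81, SE 0.21; Acaa1a at -2.52, SE 0.27) and PT segment and transport genes for 20 of 28 (Slc6a19, a neutral amino acid transporter, at -4.60, SE 0.48; Slc22a6, an organic anion transporter, at -3.49, SE 0.36). Amino acid and creatine metabolism genes fell for 14 of 17 (Hgd at -2.09, SE 0.24), androgen-responsive genes for 8 of 9 (Odc1 at -3.87, SE 0.41), PT transcription factors for 7 of 12 (Maf at -2.71, SE 0.36) and NRF2 and glutathione genes for 10 of 17, with 1 rise (Fth1, the ferritin heavy chain, at -4.91, SE 0.48). The camera adjusted p of these 7 lists was at most 0.0358. With an estimated correlation none held, at an adjusted p = 0.0747, 0.0554, 0.0554, 0.0606, 0.106, 0.202 and 0.224, in that order. Adjusted over the list alone, 10 gluconeogenesis, 22 fatty acid oxidation and 21 transport genes were lower. With the barcode set as a term NRF2 genes fell for 1 and lost their camera call (adjusted p = 0.104), fatty acid oxidation falls went from 21 to 8, transport from 20 to 13, amino acid from 14 to 8, androgen from 8 to 3 and transcription factors from 7 to 3, while cell cycle rises went from 12 to 5 and injury rises from 17 to 11; those lists kept their calls. Lists without a camera call were p53 targets, glycolysis and hypoxia, MHC and interferon, TAL identity, macrophage and leukocyte, endothelial, stromal, and collecting duct and distal genes, the last at an adjusted p of 0.0707; urothelial markers had 2 tested members and no list test. Of the distal list, Trpm6, a magnesium channel gene, rose by 5.79 (SE 0.34). Umod, the uromodulin gene of the TAL list, fell by 2.46 (SE 0.51), and Egf by 1.88 (SE 0.35). Egf had 28.7 CPM in PT-like and 6988 in TAL-like control nuclei, without TMM factors. RNA shed by other nuclei and counted with a nucleus (free RNA) could give the level in PT-like nuclei. It was not tested for these falls.

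**Figure D2:**
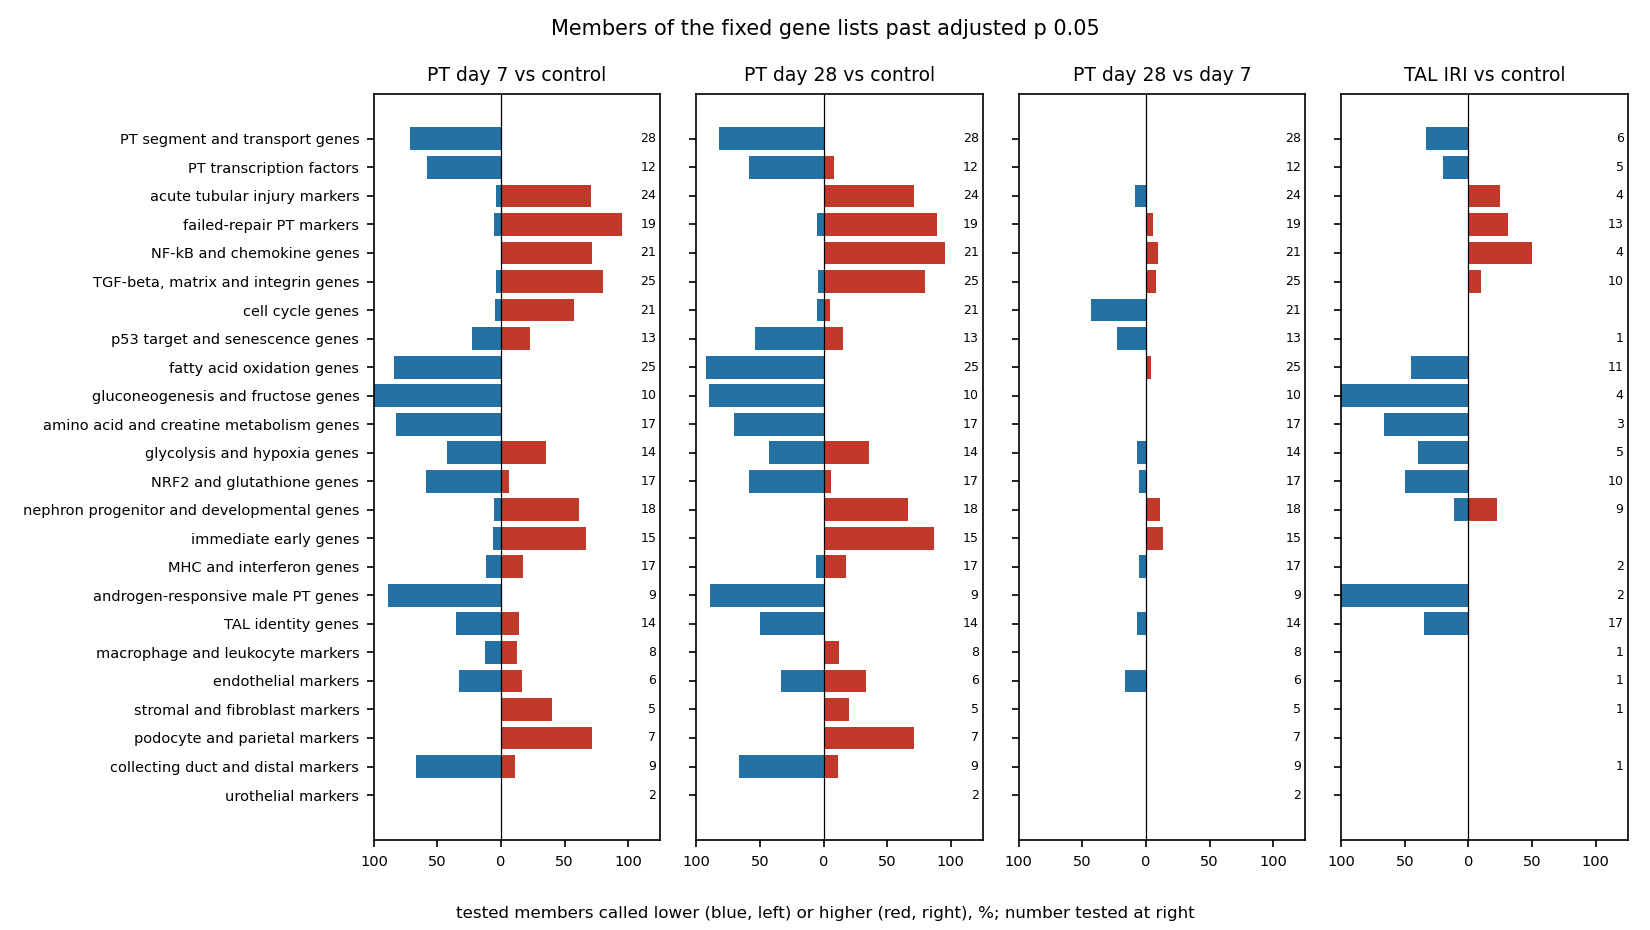
Members of each gene list that rose or fell, as a percent of members tested. Panels show PT-like sums for day 7 against control, day 28 against control and day 28 against day 7, and TAL-like sums for IRI against control. Of 21 cell cycle genes, 12 rose at day 7 against control and 9 were lower at day 28 than at day 7.

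Day 28 against control asked which of these differences stood 4 weeks after injury. Vcam1 rose by 6.47 (SE 0.41, adjusted p = 4.6e-07), from 6.96 ± 3.38 to 571 ± 170 CPM (SD, n = 3), and Havcr1 by 5.55 (SE 0.39, adjusted p = 9.0e-07), to 273 ± 69.3 CPM. The monocyte chemokine gene Ccl2 rose by 6.90 (SE 0.64, adjusted p = 6.8e-06), from 0.857 ± 0.587 to 128 ± 113 CPM; its day 28 libraries stood at 259, 59.5 and 65.4 CPM, and a predicted gene, Gm17268, lies across it on the other strand. Spp1 rose by 2.85 (SE 0.31) and Krt20 by 2.78 (SE 0.57, adjusted p = 0.0019). Slc34a1 fell by 2.63 (SE 0.30, adjusted p = 3.5e-05), Lrp2 by 1.5 (SE 0.23, adjusted p = 2.6e-04) and Hnf4a by 0.70 (SE 0.20, adjusted p = 0.013). Each of the 3 day 28 libraries lay outside the range of the 4 controls for these 8 genes. Of them, Vcam1, Havcr1, Spp1, Krt20, Slc34a1 and Lrp2 are among the markers that named the PT-like clusters, with the limit given for day 7.

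In all, 3406 genes rose and 3007 fell among the 14264 tested. The potassium channel gene Kcnh8 rose by 7.87 (SE 0.32), the sorting receptor gene Sorcs1 by 7.54 (SE 0.43) and Runx1 by 7.33 (SE 0.32), and Sox9 had 64.0 ± 11.2 CPM against 0.110 ± 0.220. Col6a6 fell by 7.15 (SE 0.55), Ugt1a10 by 7.45 (SE 0.71) and Ftcd, a folate enzyme gene, by 6.46 (SE 0.52). Within v2 barcodes, day 28 mouse 1 against the 4 controls, 1977 genes passed, with Vcam1 at 6.80, Havcr1 at 5.75, Ccl2 at 7.92 and Slc34a1 at -2.28, while Lrp2 (-1.25, adjusted p = 0.071), Hnf4a (-1.08, adjusted p = 0.059) and Caln1 (-3.75, adjusted p = 0.070) lost their calls. The lone IRI library is assumed there to vary as the controls did. That mouse also had the highest serum creatinine of the IRI mice at 48 h, 0.488 mg/dL against 0.133 to 0.255, so values within v2 barcodes and with the barcode term do not separate the barcode set from the severity of injury. With the barcode set as a term, 3046 genes passed. The median log2 change followed gene length: over 5 groups of genes from the shortest to the longest spans it went from -0.65 to 0.30, and with the barcode term from -0.22 to 0.14. At day 7 against control it went from -0.96 to 0.53, and with the barcode term from -0.26 to 0.19. For day 28 against day 7 it ran the other way, from 0.32 to -0.20. Both IRI times share the 4 controls: 2655 genes were higher and 2271 lower at both times, and 93 went opposite ways. The log2 changes correlated at 0.797 across genes (genes are not independent replicates), against 0.402 in simulated unchanged groups. That simulation models the shared controls alone. Both IRI times also share reporter line and sort and, but for day 28 mouse 1, v3 barcodes. The gap between the correlations therefore does not single out injury.

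**Figure D3:**
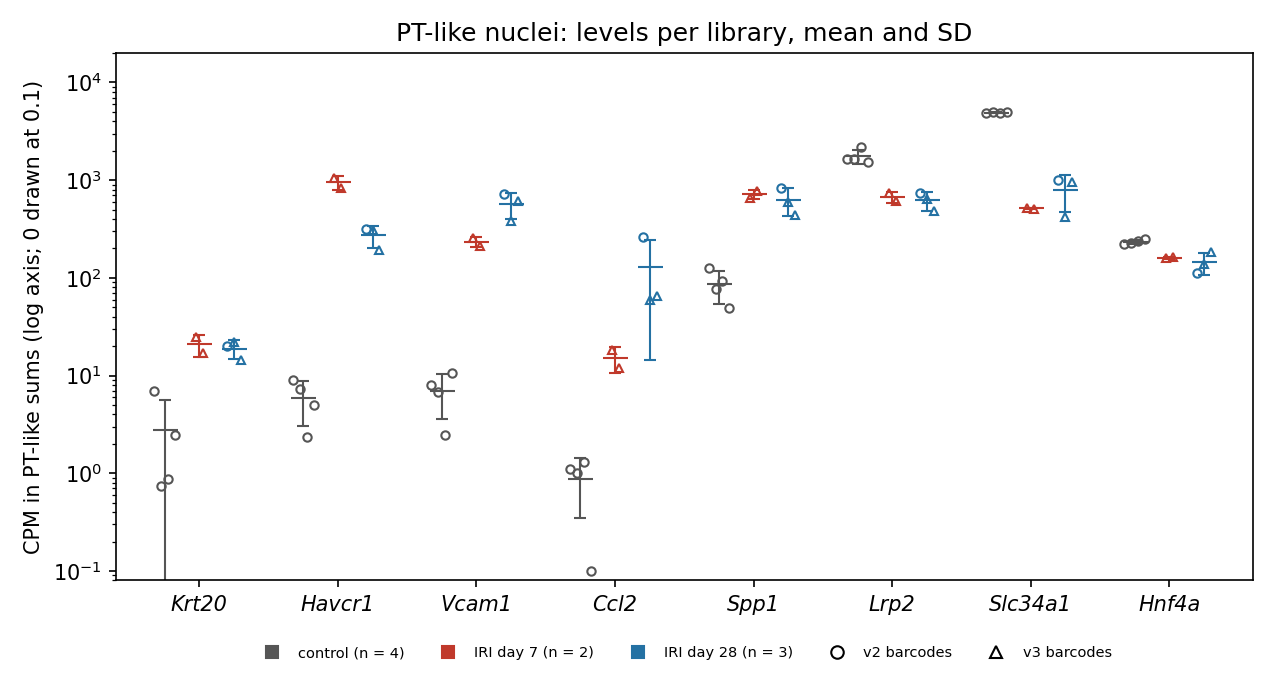
CPM in PT-like sums of 8 genes named in advance, on a log axis, with 1 point per library and bars at the group means. Havcr1 averaged 5.87 CPM in control, 951 at day 7 and 273 at day 28, and Vcam1 6.96, 233 and 571.

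Inflammatory and repair lists stayed above control at day 28. NF-kB and chemokine genes rose for 20 of 21 (Il34 at 3.54, SE 0.22; Nfkb1 at 3.03, SE 0.21), failed-repair markers for 17 of 19 with 1 fall (Dock10 at 5.32, SE 0.22; Cp at 5.19, SE 0.26) and TGF-beta, matrix and integrin genes for 20 of 25 with 1 fall (Tgfb2, a TGF-beta ligand, at 6.22, SE 0.39). Nephron progenitor genes rose for 12 of 18 (Cdh6 at 5.93, SE 0.26), injury markers for 17 of 24, immediate early genes for 13 of 15 (Klf6 at 2.91, SE 0.25) and podocyte and parietal markers for 5 of 7 (Wt1 at 5.53, SE 0.43). Fatty acid oxidation genes fell for 23 of 25 (Acaa1a at -3.26, SE 0.25), transport genes for 23 of 28 (Aqp1, a water channel, at -3.13, SE 0.33), amino acid metabolism genes for 12 of 17 (Prodh2 at -3.15, SE 0.30) and gluconeogenesis genes for 9 of 10. NRF2 genes fell for 10 of 17 with 1 rise (Gpx3, a secreted glutathione peroxidase, at -3.75, SE 0.48), androgen-responsive genes for 8 of 9, PT transcription factors for 7 of 12 with 1 rise (Esrra at -1.63, SE 0.23), TAL identity genes for 7 of 14 and collecting duct and distal markers for 6 of 9 with 1 rise. These 16 lists had a camera adjusted p of at most 0.0241. Falls of TAL identity and distal genes in PT-like sums carry the limit of free RNA given for day 7. Held with an estimated correlation were failed repair, progenitor and transport (adjusted p = 0.0435 each) and TGF-beta, fatty acid oxidation and amino acid metabolism (adjusted p = 0.0454 each). Lost were NF-kB and gluconeogenesis (adjusted p = 0.0699 each with an estimated correlation), podocyte (adjusted p = 0.0886), injury (adjusted p = 0.0972), androgen (adjusted p = 0.104), NRF2 (adjusted p = 0.105), PT transcription factors and distal (adjusted p = 0.144 each), immediate early (adjusted p = 0.166) and TAL identity (adjusted p = 0.329). Cell cycle genes had 1 rise (Anln at 1.90, SE 0.37) and 1 fall (Ccna2 at -3.81, SE 0.41) in 21, with a camera adjusted p of 0.865. Adjusted over the list alone, 20 NF-kB, 17 failed-repair and 21 TGF-beta genes were higher and 24 transport and 23 fatty acid oxidation genes lower. With the barcode set as a term TAL identity (1 fall, adjusted p = 0.206) and distal genes (2 falls, adjusted p = 0.621) lost their camera calls, and fatty acid oxidation falls went from 23 to 15, androgen from 8 to 4 and injury rises from 17 to 12.

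Day 28 against day 7 compared mice of the same reporter and sort and asked how traced PT nuclei changed over those 3 weeks. The nuclei of the 2 times lay largely in different clusters: the 5 clusters that each held over 10% of PT-like nuclei in both day 7 libraries held 84.5% and 86.8% of them there, against 0.957%, 10.9% and 8.40% in the day 28 libraries. The sums therefore set different mixes of states against each other, and shifts within a state were not tested apart. Proliferation genes fell: Cenpf, a kinetochore gene, by 3.89 (SE 0.52, adjusted p = 0.0016), from 30.0 ± 0.845 to 2.27 ± 1.32 CPM, Anln by 2.59 (SE 0.34) and the formin gene Diaph3 by 2.60 (SE 0.34), and Havcr1 fell by 1.80 (SE 0.37, adjusted p = 0.015). Ccl2 rose by 3.04 (SE 0.61, adjusted p = 0.013), from 15.2 ± 4.61 to 128 ± 113 CPM. Cdh13, a cadherin gene, fell by 3.15 (SE 0.36) and Hmga2, a chromatin gene of growing cells, by 3.34 (SE 0.60). Tgfb2 rose by 1.89 (SE 0.35, adjusted p = 0.0079), as did the chemokine gene Cxcl16 by 1.25 (SE 0.25, adjusted p = 0.012). Vcam1 did not pass (1.29, SE 0.41, adjusted p = 0.088), nor did Krt20 (-0.15, SE 0.57), Spp1 (-0.19, SE 0.35), Lrp2 (-0.12, SE 0.26), Slc34a1 (0.63, SE 0.34) or Hnf4a (-0.15, SE 0.23).

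Of 14264 genes 613 rose and 189 fell from day 7 to day 28. Of the rises, 340 lay in genes covered over 50% of their span by a gene on the other strand, as did 7 of the falls. Without such genes 197 rose and 94 fell. Against control, antisense genes covered over 90% had a median log2 change of -1.71 at day 7 and 1.26 at day 28. Of the 8 largest rises, Sorbs2os (6.13, SE 0.81), Pard3bos1, Ube4bos1 and Far1os (4.55, SE 0.57) are antisense transcripts across Sorbs2, Pard3b, Ube4b and Far1, and whether reads of those genes were counted in them is uncertain. The rest were B3galt2 at 5.88 (SE 0.82), Slc24a5 at 5.44 (SE 0.90), Spink2 at 5.48 (SE 1.27) and Kcnab1 at 4.41 (SE 0.64); of these only Spink2 has no gene on the other strand, since Cdc73 overlaps B3galt2, Myef2 overlaps Slc24a5, and A330015K06Rik and A730090N16Rik overlap Kcnab1. In the 4 v3 libraries alone, 2 against 2, 1269 genes rose and 706 fell, with Havcr1 at -1.85, Ccl2 at 2.08, Cenpf at -4.11 and Vcam1 at 1.15 (adjusted p = 0.013). Both day 7 mice decided calls: without mouse 1, 334 genes passed, without mouse 2, 154 did, and Havcr1 (adjusted p = 0.11 and 0.078) and Ccl2 (adjusted p = 0.071 and 0.20) lost theirs either way.

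Cell cycle genes formed the list that fell most from day 7 to day 28. Of 21 members 9 fell and none rose (11 adjusted over the list alone), including Ect2, a cytokinesis gene, at -1.74 (SE 0.28). The camera adjusted p was 1.6e-11, and the call was lost with an estimated correlation (adjusted p = 0.174). The fry test gave 0.0031, but it asks whether the list changed at all, not whether it changed more than other genes. Among p53 targets 3 of 13 fell, namely Zmat3 at -1.13 (SE 0.23), Eda2r at -1.48 (SE 0.34) and Mdm2 at -0.88 (SE 0.20), with a camera adjusted p of 0.0195 and an adjusted p = 0.759 with an estimated correlation. Of the transport and gluconeogenesis lists, Slc9a3 (0.97, adjusted p = 0.11), Fbp1 (1.09, adjusted p = 0.066) and Pck1 (1.56, adjusted p = 0.081) did not pass. Acsm1, a fatty acid enzyme gene, rose by 3.25 (SE 0.73), with 1001 CPM in day 28 mouse 1 and 165 and 192 in the others; the injury gene Cd44 fell by 1.28 (SE 0.28). Pkm, the pyruvate kinase gene, fell by 1.83 (SE 0.29), Acsl4 by 1.17 (SE 0.26), and Zfp36, which encodes an mRNA decay factor, rose by 2.35 (SE 0.43).

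**Figure D4:**
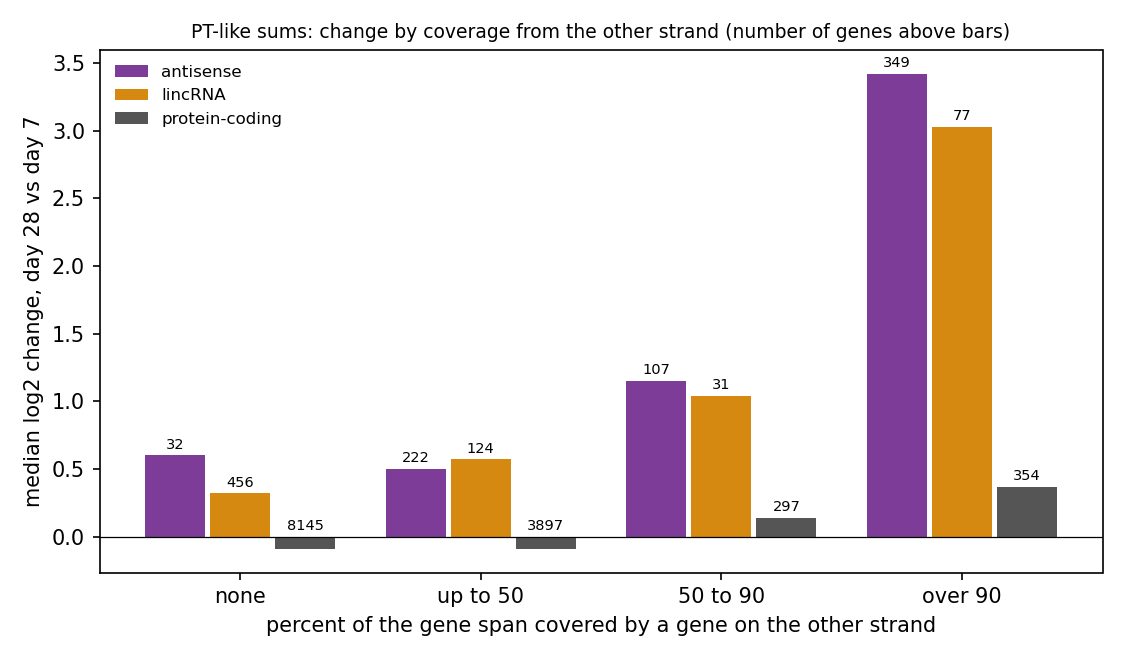
Log2 change from day 7 to day 28 in PT-like sums by how much of a gene's span is covered by a gene on the other strand. Antisense genes covered over 90% had a median of 3.42 and uncovered protein-coding genes one of -0.09.

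Uninjured-state nuclei were compared to ask whether PT nuclei of day 28 mice that clustered as uninjured still differed from control. They made up 23.5%, 4.90% and 11.5% of the PT-like nuclei of the day 28 mice and 99.8% to 99.9% in controls. They lay in different clusters: 1 cluster with 0 control nuclei held 158 of the 163 such nuclei of day 28 mouse 2 and all but 2 of those of mouse 3, but 14 of the 319 of mouse 1. For mice 2 and 3 the comparison therefore set that cluster against the clusters of the controls. That cluster also held 230 and 201 nuclei of the day 7 mice, so all but 14 of its nuclei came from v3 libraries. Mouse 1, with the v2 barcodes of the controls, had its other uninjured-state nuclei in clusters that held control nuclei. The split thus went with the barcode set, and a lasting difference from control cannot be told apart from it there. Pdgfd rose by 4.32 (SE 0.34, adjusted p = 3.0e-05), from 8.07 ± 3.71 to 161 ± 24.96 CPM, and the transcription factor gene Npas3 by 7.08 (SE 0.34), from 1.88 ± 1.01 to 230 ± 75.7 CPM. Sorcs1 rose by 4.63 (SE 0.45), Rnf180 by 4.64 (SE 0.49) and Vcam1 by 2.53 (SE 0.62, adjusted p = 0.019). Col6a6 fell by 4.54 (SE 0.36) and Ftcd by 4.34 (SE 0.38); Ugt1a10, with 141 ± 69.8 CPM in control, had 0 UMIs at day 28, at least 67.7-fold lower against a floor of 3 UMIs over the group. Slc34a1 (-0.29, SE 0.23), Lrp2 (0.25, SE 0.21), Spp1 (0.24, SE 0.35) and Havcr1 (1.68, SE 0.57, adjusted p = 0.066) did not pass, while Hnf4a rose by 0.78 (SE 0.24, adjusted p = 0.046). Slc34a1, Lrp2, Spp1, Havcr1 and Vcam1 are among the markers whose scores chose these clusters. Levels of these genes near control were therefore favoured by the choice and are no evidence of recovery. Of 9413 genes, 670 rose and 642 fell; the balance moved with the setting, to 617 and 967 without a low-count filter and 568 and 330 with voom.

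How nuclei were split into states moved this result. With 4 other random seeds of the clustering, 24.0% to 26.7%, 5.33% to 10.0% and 12.3% to 17.1% of PT-like nuclei of the 3 day 28 mice were uninjured-state, and 1420, 2604, 1383 and 1739 genes passed. Npas3 changed by 6.95 to 7.03, Pdgfd by 4.51 to 5.62 and Vcam1 by 2.88 to 4.46 under those seeds, with a call each time. Havcr1, without a call at first, changed by 1.81 to 3.71 and passed under all 4, and Hnf4a, at 0.42 to 0.69, lost its call under all 4. Under seed 2 alone Spp1 passed at 1.17 (adjusted p = 0.014) and Slc34a1 at -0.73 (adjusted p = 0.038). How far injured nuclei entered the uninjured-state clusters of day 28 mice is therefore open.

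Among the lists, 4 of 12 nephron progenitor genes rose (Prom1 at 1.78, SE 0.31; Pax2 at 1.20, SE 0.21), and 6 of 25 fatty acid oxidation genes fell (Acaa1a at -2.58, SE 0.31), as did 5 of 14 NRF2 genes (Fth1 at -2.12, SE 0.27) and 3 of 8 p53 targets. Adjusted over the list alone these counts were 5, 9, 7 and 5. Each list had a camera call (adjusted p of 0.0014, 8.2e-04, 8.3e-04 and 0.0071), lost with an estimated correlation at an adjusted p = 0.146, 0.215, 0.146 and 0.146. Failed-repair genes rose for 5 of 16 and fell for 2 without a camera call (adjusted p of 0.164), and 3 transport genes fell and 3 rose of 28. With the barcode set as a term p53 targets had no fall and no camera call (adjusted p = 0.0591), fatty acid oxidation and NRF2 genes kept 1 fall each, and failed-repair genes gained a call (adjusted p = 0.0283). With that term 76 genes rose and 24 fell, and within v2 barcodes 30 rose and 4 fell; Pdgfd, Npas3, Sorcs1, Col6a6 and Ftcd passed both times, Vcam1 changed by 3.53 within v2 (adjusted p = 0.047), and Hnf4a lost its call at 0.05. Without day 28 mouse 2 or mouse 3, 511 and 577 genes passed, without control 2, 787, and without day 28 mouse 1, 2166, while Vcam1 then lost its call at 1.41.

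TAL-like nuclei gave a second tubule segment from the same sorts. An unnamed cluster with TAL and distal markers and an injured proximal tubule score of 1.62 was left out. It held 228 and 210 nuclei of the day 7 mice, where 61 and 37 nuclei were TAL-like, and 2 of control 1. Its nuclei had a median of 4201 UMIs, and a median of 1.72 times the median depth of their library. Doublets could give such depth, and this was not tested. Another left-out cluster, with TAL and PT markers, held 132, 47, 92 and 62 nuclei of controls 1 to 4 and 12 of day 28 mouse 1. Etl4 rose by 2.18 (SE 0.33, adjusted p = 2.2e-04) and the failed-repair gene Dcdc2a by 2.34 (SE 0.45, adjusted p = 0.0016). Il34, a macrophage growth factor gene, rose by 1.30 (SE 0.26, adjusted p = 0.0023). Il34 rose in PT-like sums too, and free RNA of the IRI sorts was not weighed for rises in TAL-like nuclei. Slc34a1, a proximal tubule gene, fell by 4.66 (SE 0.35, adjusted p = 5.0e-08), from 662 ± 262 CPM in control to 20.7 ± 3.84 at day 7 and 30.5 ± 8.81 at day 28, and Fth1 by 3.62 (SE 0.34). TAL genes fell as well: Egf, the epidermal growth factor gene, by 1.56 (SE 0.25, adjusted p = 3.9e-04) and Umod by 1.15 (SE 0.25). The kinase gene Wnk1, which had more CPM without TMM factors in distal-like (3340) than in TAL-like (877) control nuclei, fell by 1.49 (SE 0.23). Spp1 was close to unchanged (-0.02, SE 0.30) and its sign depended on the setting. Of 3429 genes, 93 rose and 317 fell. Of the falls, 46 (14.5%) were genes with at least 2 times as many CPM in PT-like as in TAL-like control nuclei, as were 14% of the rises and 8.84% of the genes tested, and 70 falls carried mitochondrial or ribosomal protein names. Over all nuclei, mitochondrial transcripts took 0.0715% to 0.1997% of UMIs in v2 and 0.00855% to 0.0118% in v3 libraries, and ribosomal protein genes 0.405% to 0.826% and 0.159% to 0.226%. Day 28 mouse 1, with v2 barcodes, stood at 0.0715% and 0.405%. That was nearer to the controls (0.0818% to 0.1997% and 0.485% to 0.826%) than to the v3 libraries. These shares thus went largely with the barcode set, as far as 1 IRI library can show. An effect of injury on these falls is not separated from it. The median span was 10370 bases for falls and 189500 for rises.

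By list, fatty acid oxidation genes fell for 5 of 11 in TAL-like sums, gluconeogenesis genes for 4 of 4, amino acid metabolism genes for 2 of 3, NRF2 genes for 5 of 10 and TAL identity genes for 6 of 17, and failed-repair genes rose for 4 of 13, NF-kB genes for 2 of 4 (Nfkb1 at 1.17, SE 0.35) and TGF-beta genes for 1 of 10 (Tgfbr1 at 1.30, SE 0.35). Adjusted over the list alone these counts were 7, 4, 3, 5, 6, 5, 2 and 2. The failed-repair, NF-kB and TGF-beta lists rose in PT-like sums too. Free RNA from PT-like nuclei was not weighed for their rises in TAL-like sums. The camera adjusted p was at most 0.0281 and lost with an estimated correlation, at an adjusted p = 0.0597, 0.0597, 0.104, 0.192, 0.104, 0.104, 0.257 and 0.104. With the barcode set as a term no member of these 8 lists passed, and camera calls ended for amino acid metabolism (adjusted p = 0.342), NRF2 (adjusted p = 0.733) and TAL identity (adjusted p = 0.108). With it 1 gene passed, Slc34a1 at -5.32, and 71 passed with a minimum count of 50, 127 without nuclei under 1000 UMIs, 228 without day 7 mouse 1 and 264 without either day 28 mouse 2 or mouse 3. TAL-like sums held 45432 to 322294 UMIs per library over genes tested.

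The PT minus TAL difference in the IRI effect was tested directly. PT-like sums held 11 clusters with the injured score higher, while the unnamed cluster with TAL and injury markers was left out of the TAL-like sums. Whether that cluster holds injured TAL nuclei or doublets was not tested. The 2 sides may thus be unlike in the injured nuclei they hold. Vcam1, Spp1 and Cdh6 are among the markers that named the PT-like clusters. Pdgfd rose more in PT-like than in TAL-like nuclei by 7.07 (SE 0.27), with means of 11.7 and 1464 CPM in control and IRI PT-like sums and 755 and 770 in TAL-like sums. Cdh6, an embryonic cadherin gene, differed by 6.30 (SE 0.33), Dock10 by 5.17 (SE 0.50), Psd3 by 4.04 (SE 0.31), Anxa2 by 3.56 (SE 0.43) and Spp1 by 2.55 (SE 0.26), each toward PT. Slc34a1 differed by 1.28 (SE 0.43, adjusted p = 0.038), having fallen in both, and Umod by -1.73 (SE 0.24). Free RNA may enter Slc34a1 in TAL-like nuclei, and Umod and the TAL identity list in PT-like nuclei. Slc34a1 kept its direction but lost its call in 10 of 23 alternatives, among them DESeq2, thinned sums and the barcode term. Ccl2 had 93.2 CPM in IRI PT-like sums against 0.999 in control, with 2 UMIs in TAL-like nuclei of each arm. Vcam1 differed by 3.85 toward PT, but by -0.42 in thinned sums and -3.31 without control 1, so its direction is open. Of the 19 genes named here by size or in advance that passed, 17 lost their call under at least 1 alternative. Of 12408 genes, 574 differed toward PT and 406 toward TAL, against 492 and 166 with DESeq2, 422 and 131 without day 7 mouse 1, and 358 and 365 without control 1.

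Lists that differed toward PT were failed-repair markers (14 of 19), TGF-beta genes (7 of 25, with 1 the other way), injury markers (6 of 22), NF-kB genes (6 of 20), nephron progenitor genes (5 of 16), immediate early genes (2 of 13) and podocyte markers (1 of 7). Toward TAL differed fatty acid oxidation genes (5 of 25; Acsl1 at -1.29, SE 0.27), PT transcription factors (4 of 12; Ppara at -1.98, SE 0.35), PT transport genes (3 of 28, with 1 the other way) and TAL identity genes (5 of 17, with 2 the other way). Adjusted over the list alone, 17 failed-repair, 10 TGF-beta and 7 injury genes differed toward PT. With an estimated correlation the first 6 lists and fatty acid oxidation held (adjusted p from 0.0127 to 0.0443), and podocyte (adjusted p = 0.107), PT transcription factors (adjusted p = 0.107), transport (adjusted p = 0.172) and TAL identity (adjusted p = 0.304) did not. The transport list had a median of 0.57 and the fatty acid oxidation list a mean of 0.06, opposite in sign to their tests, and TAL identity turned toward PT with the barcode set as a term. That term also ended the camera calls of transport (adjusted p = 0.473), PT transcription factors and fatty acid oxidation (adjusted p = 0.0653 each) and left 8 failed-repair genes. With that term 170 genes passed; 553 passed without day 7 mouse 1 and 497 in thinned sums.

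How many traced nuclei carried injury transcripts was asked per nucleus, at 500 UMIs each. Havcr1, Vcam1, Spp1 and Krt20 are among the markers that named the PT-like clusters. Their shares in IRI PT-like nuclei were therefore favoured by that choice. Havcr1 was seen in 33.8% ± 1.85 (n = 2) of PT-like nuclei at day 7 and 10.8% ± 2.60 (n = 3) at day 28, and Vcam1 in 9.55% ± 0.499 and 19.2% ± 4.76 (two-sided exact permutation p = 0.1 and 0.2, where 0.1 is the smallest possible). Over both times Havcr1 was seen in 19.99% ± 12.8 (n = 5) against 0.240% ± 0.128 (n = 4) in control (exact permutation p = 0.0159, adjusted 0.0212), and Vcam1 in 15.3% ± 6.25 against 0.336% ± 0.201 (exact permutation p = 0.00794, the smallest possible, adjusted 0.0159). Spp1 was seen in 24.9% ± 5.35 of IRI and 3.33% ± 1.20 of control nuclei, Krt20 in 0.925% ± 0.270 and 0.0853% ± 0.0552, Slc34a1 in 19.1% ± 4.30 and 83.5% ± 1.92, and Lrp2 in 23.3% ± 3.06 and 53.03% ± 2.05, with an adjusted p of 0.0212 for Krt20 and 0.0159 for the rest. A cycling marker was seen in 4.21% ± 0.343 at day 7 and 1.20% ± 1.08 at day 28 (exact permutation p = 0.2). Ccl2 was seen in 3.05% ± 3.03 of IRI and 0.0268% ± 0.0392 of control nuclei (exact permutation p = 0.0556). In TAL-like nuclei, where free RNA is the background, Havcr1 was seen in 0.604% of IRI and 0% of control nuclei, Vcam1 in 1.28% and 0%, Krt20 in 0.138% and 0%, and Slc34a1 in 0.731% and 22.8%. Spp1, at 19.9% and 15.8%, is a gene that TAL nuclei express. Median depths before thinning were 1702, 2412 and 2798.5 UMIs in PT-like and 977, 1764 and 1564 in TAL-like nuclei of control, day 7 and day 28. In v2 libraries, the difference between day 28 mouse 1 and the controls was 12.8 points for Havcr1 and 19.8 for Vcam1; in v3 libraries day 28 minus day 7 was -24.1 and 9.10 points.

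**Figure D5:**
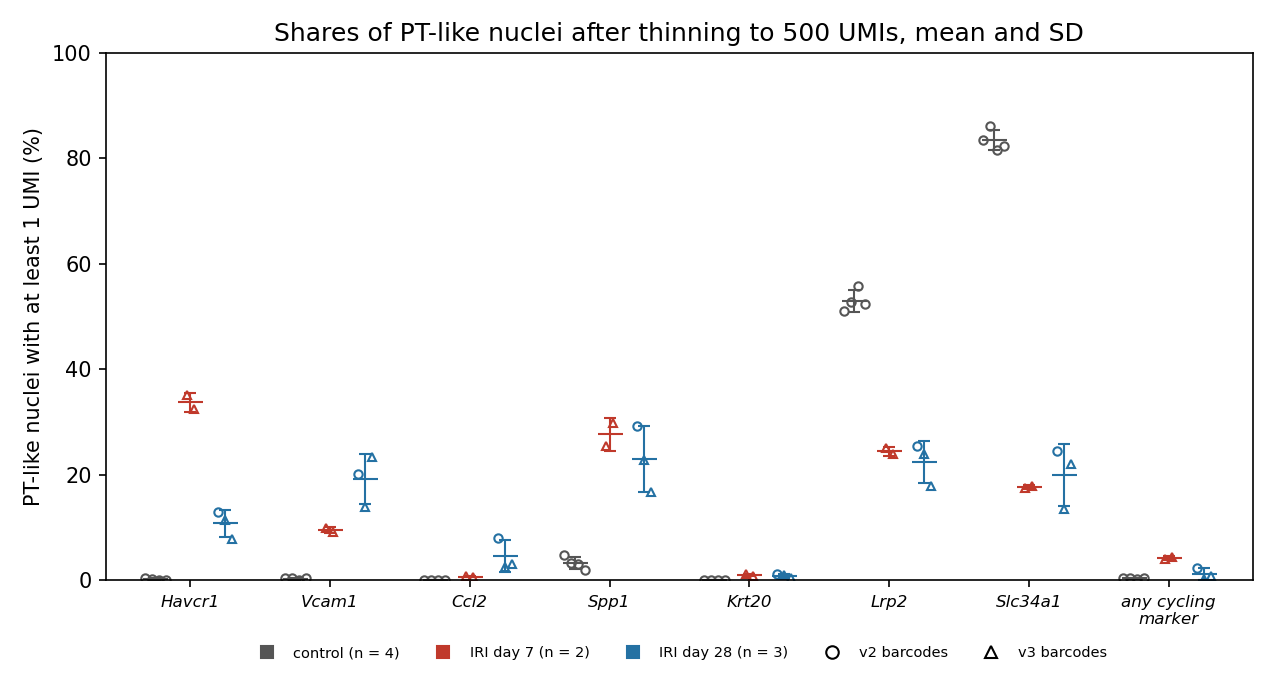
Percent of PT-like nuclei with at least 1 UMI of each gene after thinning to 500 UMIs, with 1 point per library and bars at the group means. Havcr1 averaged 33.8% at day 7 and 10.8% at day 28, against 0.240% in control.

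On the mm10 assembly Havcr1 lies on chromosome 11 from 46735080 to 46779578, Vcam1 on chromosome 3 from 116109949 to 116129688, Ccl2 on chromosome 11 from 82035571 to 82037453 and Spp1 on chromosome 5 from 104435118 to 104441050. Krt20 lies on chromosome 11 from 99428403 to 99438150, Slc34a1 on chromosome 13 from 55398187 to 55415592, Lrp2 on chromosome 2 from 69424340 to 69586065 and Hnf4a on chromosome 2 from 163506808 to 163572910. Each is annotated as a protein-coding gene, and Hnf4a, Vcam1 and Ccl2 are overlapped on the other strand by Hnf4aos, Gm43109 and Gm17268.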

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

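Chosen only after the result was seen were the 4 tests of the covered genes, the test of falling genes with an excess in TAL-like nuclei, and the tests with the barcode set. In 108 control values tested, 13 (12%) had 1 library far from the other 3, where chance marks about 1 in 20. For 5 of them, Traf1, Sox9, CT010465.1, Asic2 and Syt2, the other 3 libraries had 0 and the gap is the largest by construction, so these counts near 0 mark no unusual library. In PT-like sums these were Traf1 at 0.445 CPM in control 1 and Sox9 at 0.439 CPM in control 3 (0 in the others), Caln1 at 156 CPM in control 4 (20.9 to 39.7), B3galt2 at 0.891 CPM in control 1 (4.54 to 4.98) and Ube4bos1 at 37.8 CPM in control 3 (14.9 to 18.7). In uninjured-state sums they were CT010465.1 at 1.003 CPM in control 2 (0 in the others), Caln1 at 167 CPM in control 4 (20.7 to 39.9), Hnf4a at 265 CPM in control 4 (221 to 228) and Lrp2 at 2029 CPM in control 3 (1642 to 1658). In TAL-like sums Asic2 stood at 19.3 CPM in control 2 and Syt2 at 17.1 CPM in control 1, with 0 in the others. The PT-like share was 67.0% in control 1 (86.7 to 90.7), the mouse without surgery, and the median depth was 668 UMIs per nucleus in control 4 (1722 to 1938).

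Effects differed between groups in 2 comparisons that test the difference itself. For PT minus TAL, 980 genes passed, with Spp1 at 2.55, Slc34a1 at 1.28 (a call lost in 10 of 23 alternatives), Ccl2 at 8.57 (a fitted value that rests on 2 UMIs in the TAL-like nuclei of each arm) and Vcam1 at 3.85, which turned to -3.31 without control 1. For day 28 against day 7, 802 genes passed, with Havcr1 at -1.80 and Ccl2 at 3.04. A signal outside the comparisons came from genes kept in the table of IRI nuclei alone: Xirp2 had 2200 UMIs there, Basp1 1840 and Adgra1 983. The control table does not list them, which that table's filter allows for genes with a count in fewer than 3 nuclei.

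Genes that rose from day 7 to day 28 lay often in genes covered by a gene on the other strand: 780 genes covered over 90% had a median log2 change of 1.46. Depth is argued against by thinned sums, where the median was 1.31, and the barcode set by v3 libraries alone, where it was 1.47. A rise of noncoding RNA of every kind is argued against by a gap of 2.71 between covered and uncovered lincRNA genes. A candidate explanation is that reads of the gene on the other strand were counted differently at the 2 times. The median was 2.70 higher in the highest than in the lowest of 5 groups by partner expression. Per library, the median log2 ratio of covered gene to partner was -3.45 to -3.15 in controls and -2.94 to -2.75 at day 28. It was -4.48 and -5.02 at day 7, so the change from day 7 to day 28 was in part a low level at day 7. A biological change in antisense transcription was not tested apart from this and stays open.

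Genes that fell in TAL-like nuclei of IRI mice included proximal tubule transcripts. For the 46 falling genes with PT CPM at least 2 times TAL CPM in controls, free PT RNA in the control sorts may explain the falls, since 100% of them were lower in distal-like nuclei too. That does not single it out, as 92.5% of the falls with TAL CPM above PT CPM were also lower there, against 33.0% of all genes tested. Free RNA was also set against the 17.4% of falls with over 1.5 times as many UMIs per TAL-like as per PT-like control nucleus. Were all UMIs of a PT-like nucleus free, their loss would allow a median of -0.13. The falls went beyond the allowed loss by a median of -1.39 (bootstrap 95% interval over genes -1.55 to -1.21). They did so by over 2 SE in 43 of 55, Egf and Umod among them. These genes were chosen because they were called as falls, so a median beyond the loss was close to fixed by that choice. The interval resamples genes that share the same libraries and does not measure the spread between mice. Whether free RNA is the whole cause for these genes therefore stays open. The barcode set cannot be told apart: the median of the falls was -1.23 (SE 0.755) with it as a term against -2.13 (SE 0.475). Calls ended through the wider error as well as the smaller change. Against the controls the median of the falls was -0.955 in day 28 mouse 1, with v2 barcodes. In the v3 libraries it was -1.87 and -2.07 for day 28 mice 2 and 3 and -2.21 and -2.50 for the day 7 mice. An effect of injury on the TAL stays open.

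Differences between IRI and control in PT-like sums followed injury, reporter line and sort together. Of the genes called at day 28, 98.4% had the same direction in day 28 mouse 1, which shares the controls' barcode set, but that library was part of the fit, so the share of the barcode set in their size cannot be told apart. Reporter line and sort cannot be told apart from injury either, since the number of IRI libraries with the reporter of the controls was 0.

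For 4 counts the libraries were regrouped, and only 1 split, the real one, reached the count. This argues against chance but does not exclude it, since no share below 1 in 35 or 1 in 100 was possible. For uninjured-state sums the splits cannot decide. Those nuclei were chosen by clusters built from the same counts, 1 of them with 0 control nuclei. The splits numbered 35 for PT day 28 against control (6413 genes, highest other 1036) and 35 for uninjured-state sums (1312, highest other 1). They were 100, drawn at random, for TAL-like sums (410, highest other 127, from a split that set the 4 v3 libraries and control 3 against the rest) and 100 for PT minus TAL (980, highest other 370).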

How the results depend on the processing

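Chosen only after the result was seen were the barcode set as a term, v2 or v3 libraries only, Leiden resolution 1, Leiden seeds 1 to 4, unnamed clusters counted under their best class, genes of either table, lists without the genes that named clusters, covered genes left out, no thinning, and leaving out the nuclei with the most UMIs from the sums; the cause was not tested for the changes below. An S3-only variant was not run. Thinning, which tests depth, lowered the calls by more than 1.5 times for day 28 against day 7, TAL-like sums and PT minus TAL. Of the values of named genes under alternatives, 632 of 648 at day 7, 668 of 672 at day 28, 640 of 672 for day 28 against day 7, 549 of 599 in uninjured-state sums, 412 of 451 in TAL-like sums and 402 of 519 for PT minus TAL kept direction and side of the threshold.

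Genes called moved past 1.5 times as follows. At day 7, barcode term 1938. At day 28, barcode term 3046 and v2 only 1977. For day 28 against day 7, DESeq2 1410, minimum count 50 495, thinned 464, replicate block 423, only the groups compared 430, v3 only 1975, covered genes left out 291. In uninjured-state sums, minimum count 50 748, replicate block 656, barcode term 100, v2 only 34, Leiden seed 2 2604. In TAL-like sums, no filter 617, minimum count 50 71, thinned 163, at least 1000 UMIs 127, replicate block 264, barcode term 1. For PT minus TAL, thinned 497, at least 1000 UMIs 623, barcode term 170. Leaving out 1 library gave 4516 to 8175 (day 7), 4636 to 7520 (day 28), 154 to 966 (day 28 against day 7), 511 to 2166 (uninjured-state), 228 to 482 (TAL-like) and 553 to 891 (PT minus TAL).

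Lists called with an estimated correlation numbered 0, 6, 0, 0, 0 and 7 in that order, 1 by fry for day 28 against day 7 and 7 for PT minus TAL with the barcode term, where the TAL identity list turned (adjusted p = 0.740). Class shares called were 0 with at least 1000 UMIs and 0 to 0 leaving out 1 library (with an IRI library left out, 4 against 4, no call was possible); shares of PT-like nuclei with a UMI called were 4 to 8. Shares in points, IRI minus control: PT 0.214 among nephron classes and 0.211 with at least 1000 UMIs; TAL 0.00914 with at least 1000 UMIs and 2.71 in v2 only; with unnamed clusters counted under their best class, TAL 0.724 and distal -1.49. Day 28 minus day 7: endothelium -0.299 (unnamed clusters counted), podocyte -0.0597 (at least 1000 UMIs) and -0.147 (v3 only), leukocyte -0.259 (at least 1000 UMIs), Krt20 0.0431 (replicate block), Lrp2 0.497 (no thinning) and 0.220 (replicate block). Leaving out 1 library: PT -7.65 to 0.262, TAL -2.02 to 0.790, distal -0.0464 to 1.18, intercalated -0.106 to 0.211, podocyte -0.0420 to 0.167 (IRI minus control) and -0.147 to 0.238 (day 28 minus day 7), leukocyte -0.409 to 0.342, Krt20 -0.285 to 0.0431, Lrp2 -3.56 to 0.220.

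Genes that turned, as log2: Smcp at day 7 0.38 (barcode term). Day 28 against day 7: Krt20 0.28 (replicate block), Hnf4a 0.001 (barcode term) and 0.054 (v3 only); leaving out 1 library, Krt20 -0.39 to 0.14, Lrp2 -0.26 to 0.037, Spp1 -0.45 to 0.003. In uninjured-state sums Lrp2 -0.095 (Leiden seed 2), Spp1 -0.09 (replicate block) and -0.056 to 0.54 leaving out 1 library. Spp1 in TAL-like sums 0.16 (no filter), 0.03 (mitochondrial genes and Malat1 left out), 0.047 (voom), 0.85 (barcode term), 0.001 (Leiden 1), 0.025 (seeds 3 and 4), -0.22 to 0.39 leaving out 1 library. PT minus TAL: DESeq2 Krt20 3.18, Havcr1 3.10, Lrp2 0.12; RLE Lrp2 0.097; no filter Lrp2 0.052; minimum count 50 Lrp2 0.18; thinned Pigr 0.30, Krt20 0.18, Vcam1 -0.42; at least 1000 UMIs Lrp2 0.54; Leiden seed 3 Lrp2 0.071, seed 4 0.065; barcode term Krt20 4.97, Havcr1 5.27, Lrp2 0.16, Hnf4a -0.97; leaving out 1 library, Krt20 -0.87 to 1.95, Vcam1 -3.31 to 4.24, Lrp2 -0.015 to 0.14.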

Other observations

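Serum creatinine at 48 h after IRI was given in mg/dL as 0.255 and 0.133 for the day 7 mice and 0.488, 0.208 and 0.228 for the day 28 mice, and at harvest as 0.177 and 0.149 for the day 7 mice, 0.093, 0.114 and 0.074 for the day 28 mice and 0.100 and 0.122 for controls 2 and 4. Gm42418 took 0.802% and 1.06% of UMIs in the day 7 libraries and at most 0.209% in each other library.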
